A study of Homo sapiens with 24 samples.

How the data were processed

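RNA-seq gene expression was measured in 4 POU2F3-expressing human SCLC cell lines (NCI-H1048, NCI-H211, NCI-H526 and COR-L311), each treated with DMSO, WA-68-VQ71 or BRM014, with 2 biological replicates per line and treatment and 24 libraries in 12 groups. Per the labels' protocols, cells were plated at 200000 per mL and treated for 3 days, RNA was extracted on columns with DNase treatment, libraries were made with a kit that does not keep the strand, and 150 bp paired-end reads were mapped to hg38 with STAR, with statistics by DESeq2. The versions of STAR and DESeq2, the counting tool and the gene annotation are not given in the sources used here. The authors deposited a table of read counts per gene, which are whole numbers and not normalized, and a table of FPKM values for the same libraries. From the values, the deposited FPKM equal the counts divided by gene length and by a library size proportional to the median-of-ratios size factor, and the zeros of both tables coincide, so the FPKM are not an independent measurement. Both tables hold 58735 genes, and 58207 of their identifiers matched a current gene symbol. Without strand information, reads of overlapping or antisense genes cannot be told apart, and reads of close paralogs, pseudogenes, HLA genes and mitochondrial transcripts with nuclear copies could be divided in a way that depends on the authors' counting.

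Libraries held 14147672 to 20667080 counts, and between 15427 and 17231 genes had at least 10 counts. Counts of replicate libraries differed by more than sampling noise in every group, with chi-square per degree of freedom between 4.38 and 14.1, and between 6.90 and 338 for the 264 pairs of libraries from different groups, so no library looked like a copy of another. The highest values within groups were those of NCI-H1048 with BRM014 (14.1) and with WA-68-VQ71 (10.3). TMM factors lay between 0.953 and 1.09. The labels call the replicates biological without saying how the cultures were separated, so p-values measure the spread between these cultures, pooled over the 12 groups.

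Groups, tests, gene lists, the rule for named genes and the other settings to be tried were set before the data were examined. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization, robust dispersions, genes kept by filterByExpr (minimum count 10, minimum total 15; 21227 genes) and 1 coefficient for each of the 12 groups, so that all libraries share the estimate of spread. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p below 0.05. The comparisons were each compound against DMSO in each line and in the mean of 4 lines, BRM014 against WA-68-VQ71, and F tests with 3 degrees of freedom of whether the effect of a compound differs between lines. The mean of 4 lines is tested against the spread between replicates within lines and speaks for these lines. Standard errors were derived from the quasi-likelihood fit, so they do not follow the spread within a single group. For genes with 0 counts in a group, folds are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No fold is given where both groups lie at or under the floor.

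In all, 35 gene lists with 527 members were fixed, of which 488 members passed the filter, 22 of them matched by an older symbol. They cover the tuft cell and POU2F3 programme, SWI/SNF subunits, other cell types of the lung, and stress, growth and signalling pathways. The 34 lists with at least 3 measured genes were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over lists, and again with the correlation estimated for each list. Counts adjusted over the list alone repeat the adjustment on the p-values of the members. Called lists were also compared under the other scalings.

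The genes named were POU2F3, POU2AF2, POU2AF3, ASCL2, SOX9, MYC, NEUROD1, YAP1, BRD9, SMARCA2 and SMARCA4, and some results that the rule covers are not reported here. To these were added, for each mean comparison, the 8 largest rises and 8 largest falls among protein coding genes with a symbol, an adjusted p below 0.05, the same direction in 4 lines and a mean log2 CPM of at least 2. For each line and compound the 3 largest rises and falls were added, with both treated libraries beyond both DMSO libraries, and for each test between lines the 5 genes with the smallest adjusted p. Of each list described, up to 4 members with the smallest adjusted p were eligible. Gene coordinates are those of the deposited table on hg38.

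The overlap of the compounds was set beside 8 simulations of unchanged groups against the same DMSO libraries, beside the overlap of independent lists and beside a fit with the DMSO libraries divided between the compounds. The tests were tried on simulated counts for 21227 genes, drawn from the spread fitted to these data. For each compound 200 genes were changed, all with a mean log2 CPM of at least 2. Recovery among more weakly expressed genes was thus not tried. For WA-68-VQ71 the change was the same in all 4 lines, so effects confined to 1 line were not tried there. In the mean of 4 lines 90% to 100% of these genes, changed by 0.5 or 1 on the log2 scale, were recovered and 5.29% of calls were false. For BRM014 in NCI-H1048 50% of genes at -0.5 and 54% at 0.5 were recovered, 94% at -1 and 98% at 1, with 3.27% false calls. The test between lines recovered 55.5% of changed genes, with 8 false calls among 119, and camera called the 1 changed list and 0 of the other lists tested.

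The alternatives were DESeq2 1.42.0, RLE factors or library sizes only in edgeR, no filter on low counts or a stricter one, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the 6 libraries of a line alone, the replicate number as a block, lines as replicates, each line or library left out, a threshold of 1 on the absolute log2 fold change, and, for lists, fry. Where a library was left out, genes were filtered anew and more were tested, between 22715 and 22961 for WA-68-VQ71 in the mean. A call lost there can come in part from the filter and the adjustment over more genes. Lists kept the main filter. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.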

Results

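RNA was sequenced from 4 cell lines derived from human small cell lung cancer (SCLC): NCI-H1048, NCI-H211, NCI-H526 and COR-L311. The labels describe them as expressing POU2F3, the transcription factor that specifies tuft cells, which are chemosensory cells of epithelia. Each line was treated for 72 hours with the vehicle DMSO, with WA-68-VQ71, given as a degrader of BRD9, or with BRM014, given as an inhibitor of SMARCA2 and SMARCA4. BRD9 is a subunit of non-canonical BAF, a form of the SWI/SNF chromatin remodelling complex, and SMARCA2 and SMARCA4 are the ATPases of SWI/SNF complexes. The labels print a dose of 100 nM after naming both compounds and leave open whether it also holds for WA-68-VQ71, so the comparison of the compounds is not one at doses known to match. With 2 biological replicates per line and treatment there were 24 libraries in 12 groups. Total gene counts per library ran from 14147672 to 20667080, with a median of 17224928. The question named in the series title is whether SWI/SNF activity maintains POU2F3 and is needed by these cells, and the comparisons were each compound against DMSO, the compounds against each other, and the lines against each other. Log2 fold changes are given with their standard error, levels as CPM (counts scaled to the normalized library size) with the SD of 2 libraries. The words "rose", "fell" and "changed" are used where the adjusted p was below 0.05.

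All 4 lines expressed POU2F3 (chromosome 11, 120236640 to 120319944, hg38), at 583 ± 5.0 CPM in NCI-H1048, 751 ± 9.1 in NCI-H211, 1507 ± 31 in NCI-H526 and 865 ± 28 in COR-L311 with DMSO. SOX9, a transcription factor of progenitor and tuft-like cells, stood at 469 ± 46, 157 ± 6.7, 460 ± 25 and 591 ± 44 CPM in the same order. NEUROD1, which marks a neuroendocrine form of SCLC, reached at most 2.15 ± 0.27 CPM, in COR-L311 with BRM014. The lines differed in their MYC family gene. MYC stood at 488 ± 21 CPM in NCI-H211, 465 ± 31 in COR-L311 and 123 ± 2.1 in NCI-H1048, whereas NCI-H526 had 0.19 ± 0.063 CPM of MYC and 1615 ± 20 CPM of MYCN. The first 3 principal components, with 39.1%, 29.2% and 18.3% of the variance, separated the lines, and the fourth, with 2.54%, separated BRM014 from the other treatments. Replicate libraries correlated at 0.983 to 0.990 in log2 CPM across genes, which are not independent replicates, and 19 of 24 libraries lay nearest to their own replicate. The others were DMSO or WA-68-VQ71 libraries of NCI-H526 and COR-L311, each nearest to a library of the other of these treatments in its line.

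**Figure D1:**
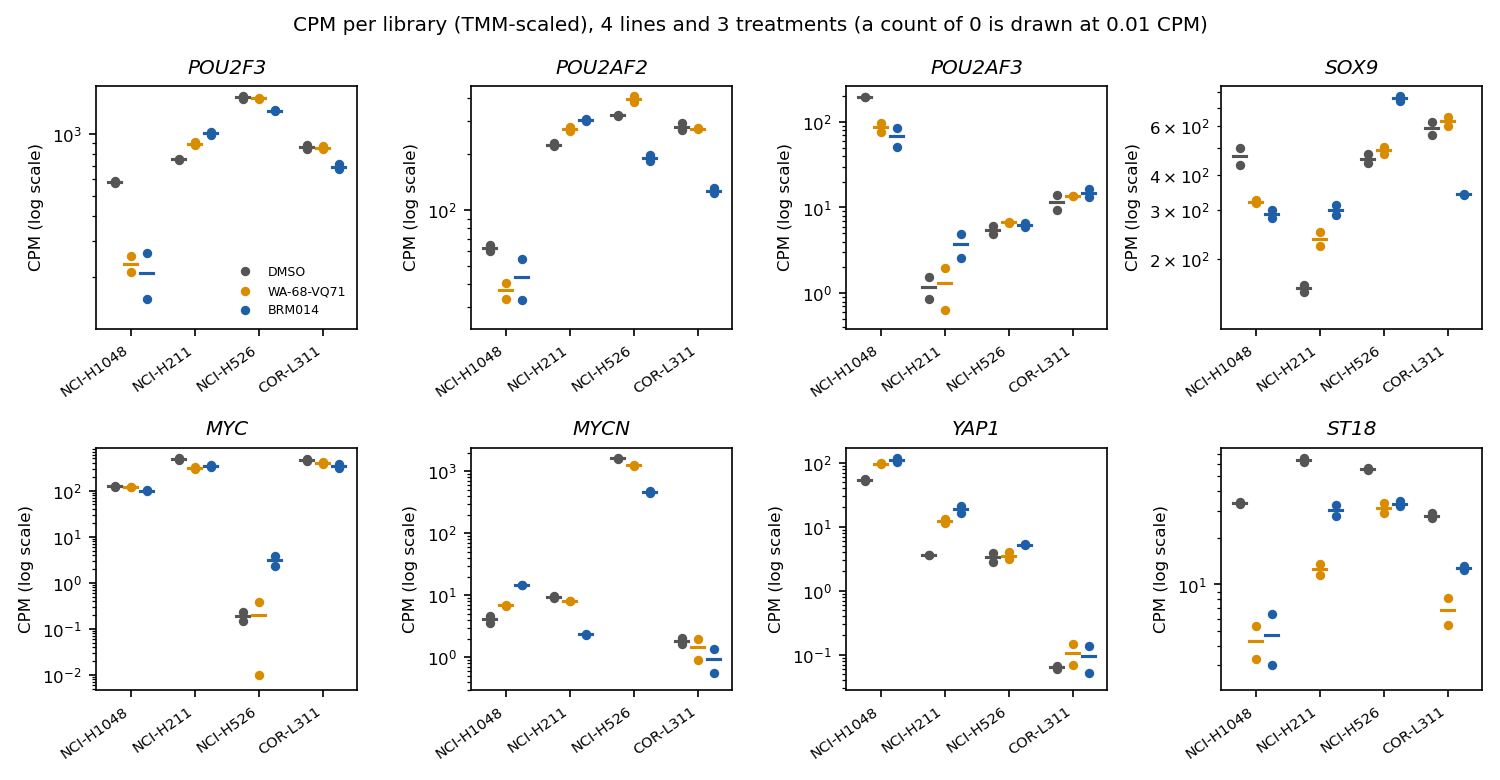
CPM of 8 genes in each of the 24 libraries by line and treatment, on a log axis with 0 drawn at 0.01; each point is a library. POU2F3 in NCI-H1048 lies at 583 CPM with DMSO, 233 with WA-68-VQ71 and 210 with BRM014, ST18 falls in all 4 lines, and MYC in NCI-H526 goes from 0.19 CPM with DMSO to 3.04 with BRM014.

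With the BRD9 degrader WA-68-VQ71, POU2F3 fell in NCI-H1048, from 583 ± 5.0 to 233 ± 31 CPM (log2 fold change -1.32 ± 0.14). Its coactivator POU2AF2 fell there by 0.76 on the log2 scale. In NCI-H211 the POU2F3 change was 0.25 ± 0.14, in NCI-H526 -0.01 ± 0.14 and in COR-L311 -0.01 ± 0.14, none of which passed the test. The effects on POU2F3 differed between the lines (F test over the 4 lines, adjusted p = 2.6e-04). POU2AF3, a further coactivator of POU2F3, fell in NCI-H1048 from 195 ± 1.9 to 87.3 ± 15 CPM (-1.16 ± 0.24), a call that ended without DMSO replicate 1 (-1.17), DMSO replicate 2 (-1.18) or WA-68-VQ71 replicate 2 (-1.01). SOX9 fell in NCI-H1048 (-0.54 ± 0.08) and rose in NCI-H211 (0.59 ± 0.08). MYC fell in NCI-H211 (-0.64 ± 0.11), though not by limma on log2(FPKM + 0.1) (adjusted p = 0.243). YAP1, the Hippo pathway coactivator, rose in NCI-H1048 (0.85 ± 0.13) and in NCI-H211 (1.76 ± 0.19). In the mean of the 4 lines POU2F3 stood at -0.27 ± 0.07 (adjusted p = 0.0364), and leaving out any 1 of the DMSO or WA-68-VQ71 libraries ended that call, with values from -0.31 to -0.24. Fits with a library left out also tested more genes, which can by itself end a call this close to the threshold. Without NCI-H1048 the mean turned to 0.079 (adjusted p = 0.195), and without COR-L311 it was -0.36 (adjusted p = 0.0522). Without NCI-H211 it was -0.46 and still called. The call was also lost with library sizes only (adjusted p = 0.0806) and without a filter on low counts (0.0852). ASCL2 (-0.35 ± 0.11, adjusted p = 0.0954), BRD9 (-0.08 ± 0.05) and SMARCA2 (0.14 ± 0.04, adjusted p = 0.0537) did not pass the test in that mean. A degrader acts on protein, so the BRD9 transcript does not check the treatment.

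ST18, a zinc finger transcription factor of the MYT1 family, had the lowest value in the mean of 4 lines among the genes named by rule for WA-68-VQ71. It fell by 2.03 ± 0.10 on the log2 scale in that mean (adjusted p = 1.5e-14) and in each line, with -2.94 in NCI-H1048, -2.36 in NCI-H211, -0.84 in NCI-H526 and -2.00 in COR-L311. In the mean a fall was also called for NEB, which encodes the muscle actin-binding protein nebulin (-0.90 ± 0.11), PSD2, an exchange factor for ARF GTPases (-0.76 ± 0.07), ANXA1, a phospholipid-binding annexin (-0.76 ± 0.06) and the glutathione peroxidase GPX2 (-0.73 ± 0.14). It was called as well for RGS13, a regulator of G protein signalling (-0.72 ± 0.14) and the succinate receptor SUCNR1 (-0.59 ± 0.10). Rises were called for CCDC9B (0.96 ± 0.13), the MAP kinase phosphatase DUSP8 (0.90 ± 0.14), SNCAIP (0.87 ± 0.17), PRR15 (0.87 ± 0.11) and NACAD (0.83 ± 0.15). Of these, DUSP8 and SNCAIP lost the mean call without NCI-H1048 (0.35 and 0.52), GPX2 and RGS13 without NCI-H211 (-0.70 and -0.83) and RGS13 also without COR-L311 (-0.64). Single lines carried much of several means that stayed called. NEB and PSD2 stood at -2.44 and -2.22 in NCI-H1048, and their means without that line were -0.39 and -0.27. ANXA1 was called in COR-L311 alone (-2.09), and its mean without that line was -0.31. Without NCI-H1048 CCDC9B stood at 0.51 and RGS13 at -0.47. BICRAL, a subunit that defines non-canonical BAF together with BRD9, rose in the mean (0.80 ± 0.08) and in each line, by 1.04, 0.77, 0.73 and 0.67 in NCI-H1048, NCI-H211, NCI-H526 and COR-L311. LARP6, FAM3B, ZFP36L1 and SEMA6A also entered by the rule, but each lost its mean call without some single library. For LARP6 this was COR-L311 WA-68-VQ71 replicate 2 (adjusted p = 0.144 without it), and for FAM3B NCI-H1048 WA-68-VQ71 replicate 1 (adjusted p = 0.226). For ZFP36L1 it was NCI-H526 DMSO replicate 1 (adjusted p = 0.0641), NCI-H526 WA-68-VQ71 replicate 1 (0.9999) or COR-L311 WA-68-VQ71 replicate 2 (0.102). SEMA6A (-0.63 ± 0.19) lost it without NCI-H211 DMSO replicate 1 (-0.60), NCI-H526 DMSO replicate 1 (-0.60) or 2 (-0.66), NCI-H526 WA-68-VQ71 replicate 2 (-0.47) or COR-L311 DMSO replicate 2 (-0.57). LARP6 had 0 counts in COR-L311 with DMSO and stood at least 3.60-fold higher with WA-68-VQ71, against 3 counts over the group, but was not called in that line (adjusted p = 0.171). FAM3B had 0 counts in NCI-H1048 with DMSO, stood at least 5.38-fold higher against the same floor and was called there (adjusted p = 0.00437). ZFP36L1, which promotes mRNA decay, rose in NCI-H1048 (0.94 ± 0.12) and NCI-H211 (1.04 ± 0.13).

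In the mean of 4 lines 1010 of 21227 tested genes changed with WA-68-VQ71, 552 higher and 458 lower, and 45 of them had a log2 fold change of at least 1 in size. Without NCI-H1048 DMSO replicate 2 the count was 667 and without the line NCI-H211 it was 409. With the 4 lines taken as the replicates edgeR called 0 genes, with 343 at an unadjusted p below 0.05. The count thus speaks for these lines. The calls were spread unevenly, with 1472 genes in NCI-H1048 (990 higher, 482 lower), 862 in NCI-H211 (430 and 432), 99 in NCI-H526 (53 and 46) and 24 in COR-L311 (12 and 12). In NCI-H1048 the count was 854 without DMSO replicate 1 and 848 without DMSO replicate 2. In NCI-H211 it was 386 without DMSO replicate 1, 300 without DMSO replicate 2, 354 without WA-68-VQ71 replicate 1 and 357 without WA-68-VQ71 replicate 2. In NCI-H526 the corresponding counts were 28, 36, 40 and 32. In COR-L311 they were 9 without DMSO replicate 1, 12 without DMSO replicate 2 and 9 without WA-68-VQ71 replicate 2. Fitted on the 6 libraries of the line alone, NCI-H211 gave 1942 genes and NCI-H1048 1222, so the order of these lines turned, and NCI-H526 gave 257. NCI-H526 gave 165 genes without a filter and 47 on log2(FPKM + 0.1), and COR-L311 gave 73 without a filter, 43 with DESeq2 and 40 on log2(FPKM + 1). Genes called in all 4 lines numbered 3, namely BICRAL, which rose, and ST18 and HMGB1P1, which fell. HMGB1P1 was named after its values were seen and is a pseudogene whose reads may be shared with HMGB1.

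**Figure D2:**
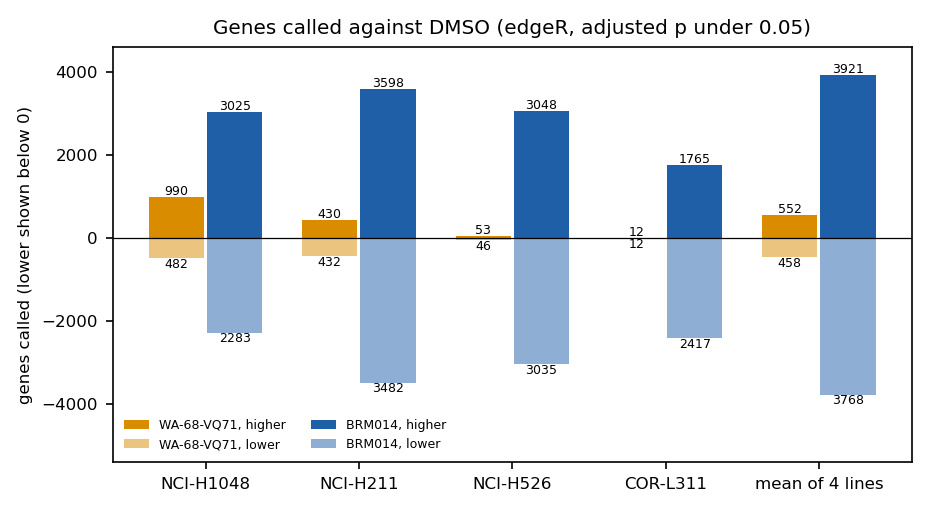
Number of genes called higher (above 0) and lower (below 0) against DMSO for each compound in each line and in the mean of 4 lines (edgeR quasi-likelihood test, adjusted p below 0.05). The bars for WA-68-VQ71 run from 24 genes in COR-L311 to 1472 in NCI-H1048 and those for BRM014 from 4182 in COR-L311 to 7689 in the mean.

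Among gene groups, ribosome biogenesis and MYC family genes fell with WA-68-VQ71 in the mean of 4 lines: 11 of 24 measured members fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 3.9e-14). Among them were BOP1 (-0.25 ± 0.04), ODC1, the ornithine decarboxylase (-0.20 ± 0.04), RRP9 (-0.29 ± 0.06) and DKC1 (-0.17 ± 0.04). This was the 1 list of the 15 called for this compound that held with an estimated correlation between genes (adjusted p = 0.0188). DNA replication and E2F targets fell (3 of 26, 7 adjusted over the list alone, adjusted p = 1.3e-06, and 0.104 with an estimated correlation). UHRF1 stood at -0.20, MCM7 at -0.13 and GINS2 at -0.21. Of 24 mitosis genes 1 fell, AURKA (-0.21 ± 0.04; 1 adjusted over the list alone), and the list was called lower (adjusted p = 8.2e-05, and 0.104 with an estimated correlation). Heat shock genes fell (3 of 12, 4 adjusted over the list alone, adjusted p = 8.4e-05, and 0.104 with an estimated correlation), led by the mitochondrial chaperones HSPD1 (-0.22 ± 0.04) and HSPE1 (-0.43 ± 0.07). Hypoxia and glycolysis genes fell too (3 of 16, 7 adjusted over the list alone, adjusted p = 7.5e-04, and 0.104 with an estimated correlation). LDHA stood at -0.19 ± 0.04.

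Cholesterol synthesis genes rose with WA-68-VQ71 (2 of 20, 8 adjusted over the list alone, adjusted p = 3.8e-06, and 0.104 with an estimated correlation). The regulator SREBF2 stood at 0.24 ± 0.04. YAP/TAZ targets rose (4 of 16, 6 adjusted over the list alone, adjusted p = 8.2e-05, and 0.144 with an estimated correlation), among them CRIM1 (0.68 ± 0.12), AJUBA (0.49 ± 0.12) and AMOTL2 (0.39 ± 0.09). Immediate early and AP-1 genes rose (4 of 21, 6 adjusted over the list alone, adjusted p = 1.1e-04, and 0.104 with an estimated correlation). EGR1 stood at 1.06 ± 0.21 and JUN at 0.33 ± 0.06. NF-kB targets rose (5 of 15, 6 adjusted over the list alone, adjusted p = 5.9e-04, and 0.177 with an estimated correlation). The feedback inhibitor TNFAIP3 stood at 1.37 ± 0.30 and RELB at 0.76 ± 0.16. MHC class I presentation genes rose (6 of 15, 8 adjusted over the list alone, adjusted p = 1.8e-04, and 0.105 with an estimated correlation). HLA-E stood at 0.43 ± 0.08, TAPBP at 0.31 ± 0.05 and ERAP1 at 0.37 ± 0.07. Epithelial keratins and junction genes rose (5 of 18, 5 adjusted over the list alone, adjusted p = 0.00588, and 0.160 with an estimated correlation). The claudin CLDN4 stood at 0.65 ± 0.07 and E-cadherin, CDH1, at 0.31 ± 0.05. The BCL2 family list rose (2 of 14, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0283, and 0.111 with an estimated correlation) through BMF (0.47 ± 0.06) and BIK (0.36 ± 0.09), which promote apoptosis. The non-canonical BAF list rose through BICRAL alone (1 of 3, 1 adjusted over the list alone, adjusted p = 0.0367, and 0.108 with an estimated correlation). In the list of IGF and receptor tyrosine kinase signalling 3 of 14 rose and 1 fell (4 and 1 adjusted over the list alone), with ERBB2 at 0.49 ± 0.06 and IRS1 at -0.28. Camera called that list higher (adjusted p = 0.0248, and 0.104 with an estimated correlation) and its median was 0.12, but its mean fitted change was -0.02. Several of the means named for these lists came largely from a single line, and the F test called a difference between lines for each gene that follows. In NCI-H1048 CLDN4 stood at 3.11 (-0.40 to 0.17 in the other lines), CDH1 at 1.35 (-0.20 to 0.10), CRIM1 at 1.98 (0.09 to 0.32), JUN at 1.29 (-0.24 to 0.17), BMF at 1.38 (-0.03 to 0.35) and EGR1 at 2.72 (-0.28 to 1.31). AJUBA stood at 2.08 in NCI-H211 (-0.29 to 0.14 in the others), HLA-E at 1.14 in NCI-H211 (0.15 to 0.23) and BIK at 1.46 in NCI-H526 (-0.57 to 0.46).

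The tuft cell and POU2F3 programme was called lower in the mean with WA-68-VQ71: 7 of 32 members fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.00548, and 0.412 with an estimated correlation). The lines went different ways. In NCI-H1048 14 of 32 members fell and 0 rose (17 and 0 adjusted over the list alone; adjusted p = 4.6e-17, and 0.0296 with an estimated correlation). These included the kinase BMX (-1.74 ± 0.15), IRAG2 (-1.59 ± 0.14) and the taste G protein subunit GNAT3 (-1.08 ± 0.16). In NCI-H211 6 members rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 6.9e-07, and 0.231 with an estimated correlation), among them CHAT, the enzyme of acetylcholine synthesis (1.20 ± 0.15), SH2D6 (1.36) and PSTPIP2 (1.16). In NCI-H526 2 members rose and 0 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0338, and 0.726 with an estimated correlation). In COR-L311 ANXA1 alone was called (-2.09 ± 0.16), and camera did not call the list.

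**Figure D3:**
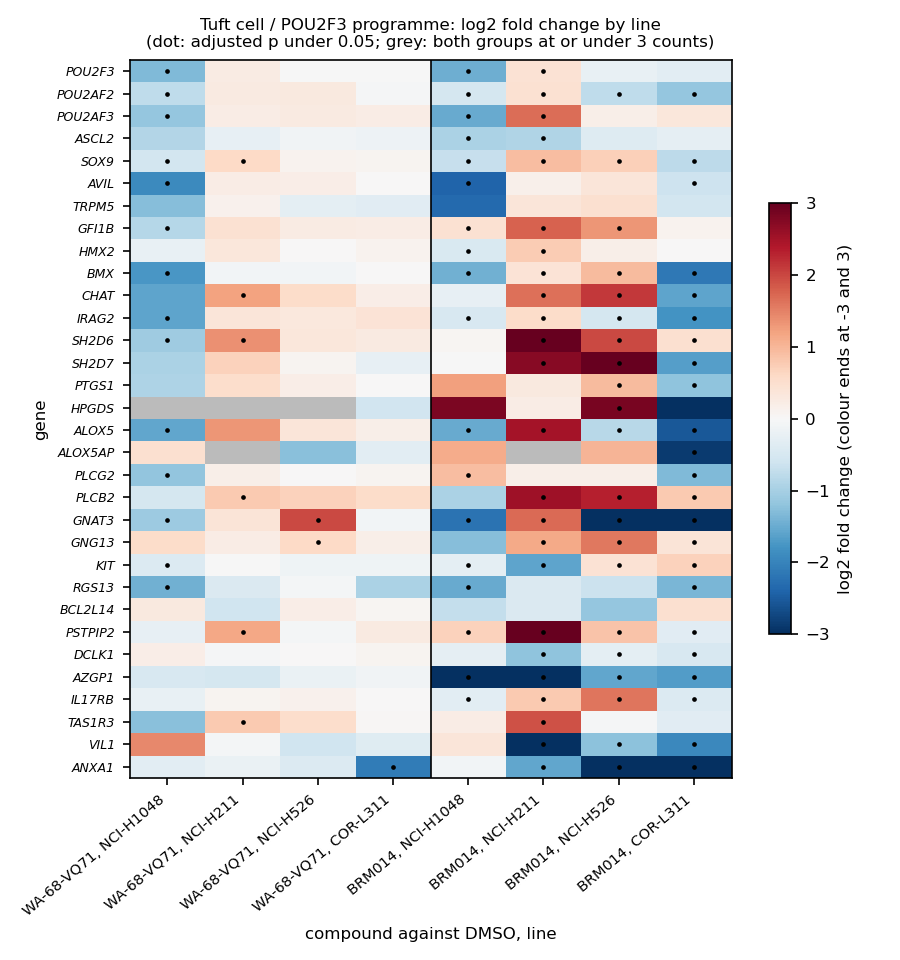
Log2 fold change against DMSO of the tuft cell and POU2F3 programme genes by compound and line, with genes whose group lies at 0 counts shown at their bound, genes with at most 3 counts in both groups in grey, and a dot where the adjusted p was below 0.05. With BRM014 3 members were called higher and 15 lower in NCI-H1048, 18 and 6 in NCI-H211, 13 and 8 in NCI-H526, and 4 and 19 in COR-L311.

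In NCI-H1048 WA-68-VQ71 raised CXCL8, the neutrophil chemokine (4.59 ± 0.37), ANKRD1, a YAP target (3.93 ± 0.21), and the stress cytokine GDF15 (3.89 ± 0.21). The largest falls named by rule were C5orf58 (-3.72 ± 0.35), ST18 and the thyroid hormone-binding protein CRYM (-2.88 ± 0.22). In this line 11 of 16 YAP/TAZ genes rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 2.8e-19). CCN1 stood at 3.29 ± 0.23 and CCN2 at 2.74 ± 0.26. NF-kB targets rose (12 of 15, 12 adjusted over the list alone, adjusted p = 1.2e-15). CCL20 stood at 4.37 and TNFAIP3 at 2.05 ± 0.23. Cholesterol synthesis genes rose (11 of 20, 17 adjusted over the list alone, adjusted p = 2.3e-15). Immediate early and AP-1 genes rose (9 of 21, with 1 lower; 12 and 1 adjusted over the list alone, adjusted p = 3.9e-07). EGR1 stood at 2.72 ± 0.18. Epithelial genes rose (8 of 18, with 1 lower; 8 and 1 adjusted over the list alone, adjusted p = 1.5e-06). CDH1 stood at 1.35. Camera called 15 lists in this line, 8 of them also with an estimated correlation, where the adjusted p of the lists just named ran from 0.0119 for YAP/TAZ targets and cholesterol synthesis to 0.0296 for epithelial and AP-1 genes.

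In NCI-H211 WA-68-VQ71 raised AJUBA, a LIM protein of the Hippo pathway (2.08 ± 0.32), YAP1 and the hyaluronan-binding protein CEMIP (1.73 ± 0.22), and lowered the bitter taste receptor gene TAS2R42 (-2.46 ± 0.40), RPS6KL1 (-2.46 ± 0.25) and ST18. Of the ribosome biogenesis and MYC family list 11 of 24 members fell and 0 rose (19 and 0 adjusted over the list alone; adjusted p = 1.9e-20, and 0.00454 with an estimated correlation), including NOP56 (-0.37) and BOP1 (-0.53). In NCI-H526 the rises named by rule were BIK, which promotes apoptosis (1.46 ± 0.18), CLIC5 (1.11 ± 0.11) and the membrane peptidase MME (1.08 ± 0.17), and the falls were MEDAG (-2.43 ± 0.35), PLA2R1 (-1.28 ± 0.28) and the matricellular protein CCN3 (-1.14 ± 0.22). MME lost its call without DMSO replicate 1 (0.91). PLA2R1 and CCN3 lost theirs without each of the 4 libraries, in the order DMSO replicates 1 and 2 and WA-68-VQ71 replicates 1 and 2, with -1.31, -1.29, -1.29 and -1.30 for PLA2R1 and -1.24, -1.07, -1.18 and -1.12 for CCN3. MYCN, the MYC family gene of this line, fell by 0.37 ± 0.09, and 2 of the 24 ribosome biogenesis and MYC family genes fell with 0 higher (4 and 0 adjusted over the list alone; adjusted p = 5.0e-10, and 0.0745 with an estimated correlation). In COR-L311 ANXA1 fell by 2.09 ± 0.16 and ST18 by 2.00, while the retinoic acid receptor gene RARG (1.38 ± 0.22), REEP2 (0.91 ± 0.17), CLIP3 (0.89 ± 0.17) and the glutamate transporter gene SLC17A8 (-1.52 ± 0.29) passed the test but lost the call without single libraries. RARG lost its call without DMSO replicate 2 (1.22), and REEP2 and CLIP3 without DMSO replicate 1 (0.84 and 0.80), DMSO replicate 2 (0.996 and 0.998) or WA-68-VQ71 replicate 2 (0.88 and 0.87). SLC17A8 lost it without each of the 4 libraries, with values from -1.57 to -1.46.

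The WA-68-VQ71 effect differed between the 4 lines for 1010 genes by the F test, and for 567 of these the highest and lowest line effects lay at least 1 apart on the log2 scale. The genes with the smallest adjusted p were ELF3, an epithelial transcription factor, CLDN4, the myosin heavy chain gene MYH9, RASSF6 and CEMIP2, and all of them moved in NCI-H1048. There ELF3 rose by 2.04 ± 0.09, against -0.08 to 0.09 in the other lines, CLDN4 by 3.11 ± 0.13, MYH9 by 1.17 and CEMIP2 by 1.49 ± 0.10, whereas RASSF6 fell by 2.39. Across 11453 genes the effects of this compound correlated between pairs of lines at -0.06 to 0.22, a description over genes that are not independent. Of 2187 genes called in any line, 1943 were called in a single line and 94 were called in opposite directions in different lines. The few calls in NCI-H526 and COR-L311 limit how many could be shared. Calls in the same direction lay above the number for independent lists in each pair of lines. In NCI-H1048 and NCI-H211 they were 80 higher and 38 lower against 20.1 and 9.81. Opposite calls also lay above it (79 against 29.9 in this pair), except in NCI-H211 and NCI-H526 (1 against 2.01).

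The SMARCA2/4 inhibitor BRM014 lowered POU2F3 in NCI-H1048 from 583 ± 5.0 to 210 ± 74 CPM (-1.47 ± 0.14) and in the mean of the 4 lines (-0.40 ± 0.07, adjusted p = 2.2e-04). Without NCI-H1048 that mean was -0.036 (adjusted p = 0.446) and no longer called, and without NCI-H211 it was -0.68. In NCI-H526 the change was -0.22 ± 0.14 and in COR-L311 -0.32 ± 0.14, neither of which passed the test. In NCI-H211 POU2F3 was higher, at 1008 ± 24 against 751 ± 9.1 CPM (0.42 ± 0.14), but this call ended without any 1 of the 4 libraries (0.43 without DMSO replicate 1, 0.42 without DMSO replicate 2, 0.41 without BRM014 replicate 1 and 0.46 without BRM014 replicate 2). The line effects differed (adjusted p = 6.8e-06). These errors pool the spread over all groups, and the BRM014 libraries of NCI-H1048 lay further apart (SD 74 CPM) than its DMSO libraries (SD 5.0 CPM). POU2AF2 fell in the mean (-0.50 ± 0.07; -0.82 without NCI-H211 and -0.28 without COR-L311), in NCI-H526 (-0.76 ± 0.13) and in COR-L311 (-1.15 ± 0.13). Its fall in NCI-H1048 (-0.53 ± 0.14) ended without DMSO replicate 1 (-0.48) or BRM014 replicate 2 (-0.21), and its rise in NCI-H211 (0.45 ± 0.13) without DMSO replicate 1 (0.41) or BRM014 replicate 2 (0.44). POU2AF3 fell in NCI-H1048 (-1.52 ± 0.24). Its rise in NCI-H211 (1.68 ± 0.58), from 1.19 ± 0.47 CPM, ended without DMSO replicate 1 (1.29), DMSO replicate 2 (2.13) or BRM014 replicate 2 (1.14). ASCL2, a transcription factor of this SCLC subtype, fell in the mean (-0.62 ± 0.11) and in NCI-H211 (-0.91 ± 0.19). Its fall in NCI-H1048 (-0.94 ± 0.27) ended without DMSO replicate 1 (-0.97), DMSO replicate 2 (-0.93) or BRM014 replicate 2 (-0.62). In NCI-H526 (-0.38 ± 0.20) and COR-L311 (-0.26 ± 0.20) it did not pass the test, and the F test called no difference between the lines (adjusted p = 0.159). SOX9 fell in NCI-H1048 (-0.69 ± 0.08) and COR-L311 (-0.79 ± 0.08) and rose in NCI-H211 (0.93 ± 0.08) and NCI-H526 (0.72 ± 0.08).

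MYC rose in NCI-H526 with BRM014 (3.89 ± 0.71), from 4 and 2 counts with DMSO to 59 and 42, while MYCN fell there from 1615 ± 20 to 464 ± 21 CPM (-1.80 ± 0.09). MYC fell in NCI-H211 (-0.51 ± 0.11), though not by limma on log2(FPKM + 0.1) (adjusted p = 0.174). In COR-L311 its fall (-0.45 ± 0.11) lost the call without DMSO replicate 2 (-0.38) or BRM014 replicate 2 (-0.30), and in NCI-H1048 (-0.32 ± 0.11) without any 1 of the 4 libraries, with values from -0.35 to -0.30. YAP1 rose in NCI-H1048 (1.04 ± 0.13) and NCI-H211 (2.37 ± 0.18). Its rise in NCI-H526 (0.63 ± 0.21) ended without BRM014 replicate 1 (0.64), DMSO replicate 2 (0.39) or BRM014 replicate 2 (0.57), and COR-L311 had at most 3 counts in each group compared. BRD9 fell in the mean (-0.24 ± 0.05), a call that ended without NCI-H526 (-0.14, adjusted p = 0.0533). Its line effects differed (F test, adjusted p = 0.00206), with a fall in NCI-H526 (-0.51 ± 0.10), a fall in NCI-H211 (-0.43 ± 0.10) that ended without BRM014 replicate 2 (-0.33), and no call in NCI-H1048 (-0.10 ± 0.10) or COR-L311 (0.07 ± 0.10). SMARCA2 fell in NCI-H211 (-0.63) and rose in COR-L311 (0.52), and its other values, 0.32 in NCI-H1048, 0.31 in NCI-H526 and 0.13 in the mean, each lost the call without some single library. These were DMSO replicate 1 (0.22) or BRM014 replicate 1 (0.19) in NCI-H1048, and BRM014 replicate 1 (0.25) or DMSO replicate 2 (0.28) in NCI-H526. For the mean they were NCI-H1048 DMSO replicate 1 (0.11), NCI-H1048 BRM014 replicate 1 (0.10) or NCI-H211 DMSO replicate 2 (0.11). The mean call of SMARCA2 also ended without NCI-H1048 (0.070), NCI-H526 (0.081) or COR-L311 (0.0016). SMARCA4 in NCI-H526 (-0.25) lost its call without DMSO replicate 1 (-0.24) or BRM014 replicate 2 (-0.23).

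HMOX1, the heme-degrading enzyme induced by oxidative stress, rose by 2.85 ± 0.08 in the mean of 4 lines (adjusted p = 8.0e-28) and in each line, for instance from 12.6 ± 0.47 to 142 ± 4.4 CPM in NCI-H526. The actin-severing protein gelsolin, GSN, rose by 2.58 ± 0.05 in the mean and also in each line, between 1.51 in NCI-H1048 and 3.60 in NCI-H526. LTBP1, which stores TGF-beta in the matrix, rose by 2.29 ± 0.10 and the secreted semaphorin SEMA3C by 2.28 ± 0.16, both in all 4 lines. The keratin gene KRT18 rose by 2.20 ± 0.05 in the mean and in every line but COR-L311, where it was at 0.17. Its start lies inside the span of KRT8 on the other strand, and the library kit keeps no strand, so reads of this pair cannot be fully told apart. THBS1, a matricellular protein, rose in NCI-H1048 (2.27 ± 0.13), NCI-H211 (2.45 ± 0.17) and NCI-H526 (6.25 ± 0.40), and in COR-L311 it went from 1 count to 42, a ratio of 39.0 with a counting interval of 6.63 to 1576. PTGS2, the inducible cyclooxygenase, had a ratio of 18.6 in COR-L311 (2.97 to 769, from 1 count). KLHDC7A rose in NCI-H211 (2.06) and NCI-H526 (1.21) and was at least 12.4-fold higher in NCI-H1048, where DMSO had 0 counts.

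COL2A1, a fibrillar collagen, fell by 2.82 ± 0.18 with BRM014 in the mean of 4 lines and in each line, from 245 ± 9.5 to 6.48 ± 1.1 CPM in COR-L311. ANXA1 fell by 2.64 ± 0.09 in the mean, with falls in NCI-H211 (-1.55), NCI-H526 (-4.60) and COR-L311 (-4.30) and no call in NCI-H1048 (-0.09). The secreted glycoprotein gene AZGP1 fell by 2.68 ± 0.38, RELN, which encodes reelin, by 2.20 ± 0.10, the protocadherin DCHS2 by 2.07 ± 0.13 and the serine protease TMPRSS3 by 2.06 ± 0.07, all in each of the 4 lines as well. The potassium channel subunit KCNS3 fell in NCI-H211 (-1.81) and NCI-H526 (-1.91) and was at least 5.75-fold lower in COR-L311, with 0 counts under BRM014. B3GAT1, the enzyme of the CD57 epitope, fell in NCI-H526 (-0.58) and COR-L311 (-0.93) and was at least 4.43-fold lower in NCI-H1048, again with 0 counts. ST18 fell in the mean (-1.44 ± 0.09) and in each line. BICRAL rose from 15.1 ± 0.032 to 36.6 ± 5.9 CPM in NCI-H1048, from 19.9 ± 1.2 to 44.8 ± 1.4 in NCI-H211, from 16.2 ± 2.7 to 50.7 ± 9.6 in NCI-H526 and from 32.2 ± 1.3 to 75.1 ± 0.61 in COR-L311.

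BRM014 changed 7689 of 21227 genes in the mean of 4 lines, 3921 higher and 3768 lower, with 1091 at a log2 fold change of at least 1 in size. Taking the lines as replicates gave 655 genes. By line there were 5308 genes in NCI-H1048 (3025 higher, 2283 lower), 7080 in NCI-H211 (3598 and 3482), 6083 in NCI-H526 (3048 and 3035) and 4182 in COR-L311 (1765 and 2417). Without normalization factors beyond the library sizes the split was 2451 higher of 5310 in NCI-H1048 and 2238 higher of 4153 in COR-L311. In NCI-H1048 the count was 3451 without DMSO replicate 1 and 3491 without BRM014 replicate 2. In COR-L311 it was 2649 without DMSO replicate 2 and 2485 without BRM014 replicate 2. In all 4 lines 688 genes were called, 170 of them higher and 183 lower in every line.

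Cell cycle and growth genes fell with BRM014 in the mean of 4 lines. All 24 mitosis genes fell (24 adjusted over the list alone; camera adjusted p = 8.4e-21, and 0.00378 with an estimated correlation), among them the mitotic kinase AURKB (-0.81 ± 0.05), KIF20A (-0.67 ± 0.04) and cyclin B2, CCNB2 (-0.67 ± 0.04). Of 26 DNA replication and E2F targets 21 fell and 2 rose (21 and 2 adjusted over the list alone; adjusted p = 2.9e-12, and 0.0331 with an estimated correlation). CDC45 stood at -0.69 ± 0.05 and MCM7 at -0.50 ± 0.04. Of 24 ribosome biogenesis and MYC family genes 21 fell and 2 rose (21 and 2 adjusted over the list alone; adjusted p = 8.1e-11, and 0.0301 with an estimated correlation). ODC1 stood at -0.82 ± 0.04, NME1 at -0.70 ± 0.05 and NPM1 at -0.53 ± 0.04. Heat shock genes fell (7 of 12, 7 adjusted over the list alone, adjusted p = 3.0e-04, and 0.0955 with an estimated correlation). HSPD1 stood at -0.71 ± 0.04. Hypoxia and glycolysis genes fell (9 of 16, with 1 higher, 9 and 1 adjusted over the list alone, adjusted p = 0.0147, and 0.232 with an estimated correlation). LDHA stood at -0.52 and PGK1 at -0.46. MHC class I presentation was lower (9 of 15 fell and 4 rose, 9 and 4 adjusted over the list alone, adjusted p = 0.0255, and 0.322 with an estimated correlation): the transactivator NLRC5 (-1.53 ± 0.09) and HLA-C (-0.80 ± 0.05) fell, while HLA-E (1.18 ± 0.08) and TAPBP (0.68) rose. HLA-C stood at -2.07 in COR-L311 and -1.12 in NCI-H526 but at 0.035 in NCI-H1048 and -0.034 in NCI-H211. HLA genes share sequence, so the division of reads among them is uncertain.

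Epithelial keratins and junction genes rose with BRM014 (10 of 18, with 2 lower; 11 and 3 adjusted over the list alone; adjusted p = 1.4e-04, and 0.0955 with an estimated correlation). KRT8 stood at 2.04 ± 0.05 and CDH1 at 1.31 ± 0.05. NF-kB targets rose (9 of 15, 9 adjusted over the list alone, adjusted p = 9.6e-04, and 0.232 with an estimated correlation). RELB stood at 1.34 ± 0.15. Immediate early and AP-1 genes rose (10 of 21, with 2 lower; 10 and 2 adjusted over the list alone; adjusted p = 0.00504, and 0.232 with an estimated correlation). FOSL2 stood at 1.55 ± 0.11 and JUNB at 0.67 ± 0.06. YAP/TAZ targets rose (7 of 16, with 2 lower; 8 and 2 adjusted over the list alone; adjusted p = 0.00546, and 0.322 with an estimated correlation). CRIM1 stood at 1.57 ± 0.11 and AMOTL2 at 1.55 ± 0.09, whereas AJUBA fell (-1.04 ± 0.15). The BCL2 family list rose (9 of 14, with 2 lower; 10 and 2 adjusted over the list alone; adjusted p = 0.0148, and 0.0955 with an estimated correlation) through BMF (0.81 ± 0.06) and PMAIP1 (0.75 ± 0.07), which promote apoptosis, and BCL2L1 (0.43), which opposes it. Some of these means join lines that went different ways: AJUBA stood at 2.60 in NCI-H211, -2.68 in NCI-H526 and -3.85 in COR-L311, AMOTL2 at -0.52 in NCI-H526 against 1.81 to 3.05 in the other lines, and PMAIP1 at -0.42 in NCI-H211 against 0.70 to 1.43. KRT8 stood at -0.065 in COR-L311 against 2.21 to 3.19 in the others, and CDH1 at 3.42 in NCI-H1048 against 0.19 to 0.89.

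**Figure D4:**
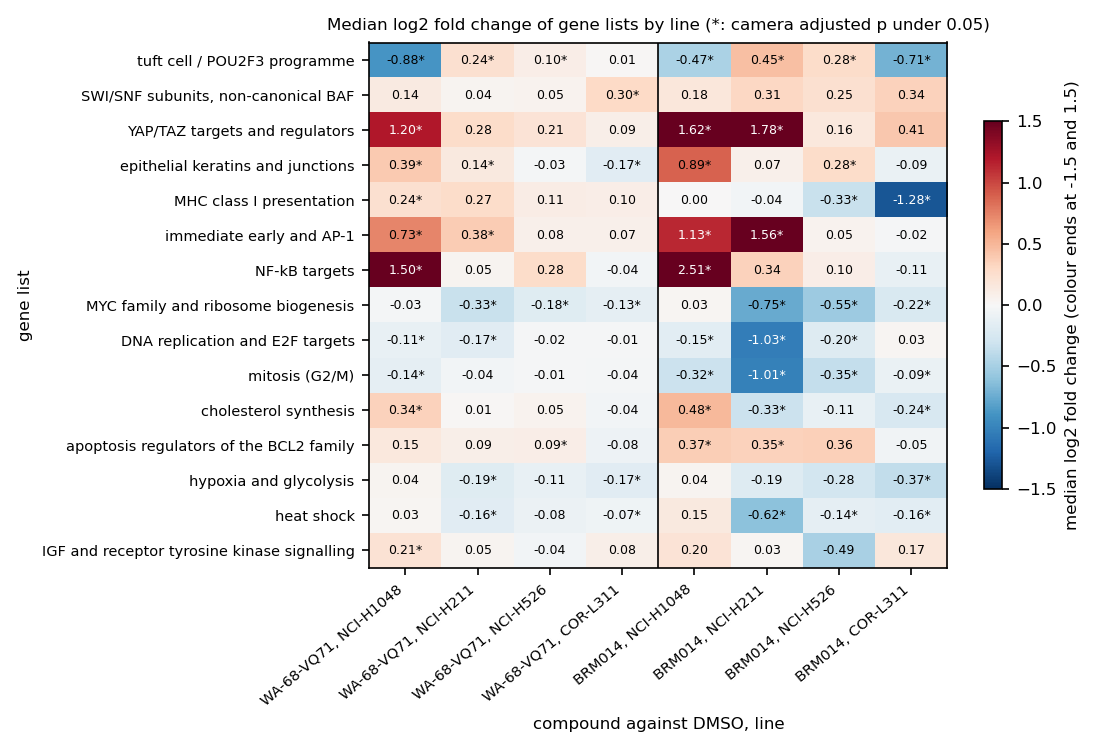
Median log2 fold change of 15 gene lists against DMSO for each compound and line, with genes whose group lies at 0 counts entered at their bound; an asterisk marks a list with a camera adjusted p below 0.05. The mitosis list is called lower with BRM014 in each line (adjusted p = 0.0245, 0.00229, 0.0336 and 0.378 with an estimated correlation in NCI-H1048, NCI-H211, NCI-H526 and COR-L311, so the call is lost in COR-L311), and the tuft cell and POU2F3 programme is called lower in NCI-H1048 and COR-L311 and higher in NCI-H211 and NCI-H526 (adjusted p = 0.281, 0.238, 0.339 and 0.683 with an estimated correlation).

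The tuft cell and POU2F3 programme was not called in the mean with BRM014 (9 of 32 higher and 13 lower, 9 and 13 adjusted over the list alone; adjusted p = 0.187), and the lines again moved different ways. In NCI-H1048 15 members fell and 3 rose (16 and 3 adjusted over the list alone; adjusted p = 1.8e-05, and 0.281 with an estimated correlation). The actin regulator AVIL stood at -2.41 ± 0.19 and GNAT3 at -2.21 ± 0.18. In COR-L311 19 fell and 4 rose (22 and 4 adjusted over the list alone; adjusted p = 2.4e-10, and 0.238 with an estimated correlation). BMX stood at -2.15 ± 0.11 and CHAT at -1.59 ± 0.15. In NCI-H211 18 rose and 6 fell (19 and 6 adjusted over the list alone; adjusted p = 6.0e-05, and 0.339 with an estimated correlation), led by PSTPIP2 (4.31 ± 0.19) and SH2D6 (4.04 ± 0.18), with GNAT3 at 1.70 ± 0.13. In NCI-H526 13 rose and 8 fell (14 and 8 adjusted over the list alone; adjusted p = 0.0446, and 0.683 with an estimated correlation). CHAT stood at 2.12 ± 0.16 and ANXA1 at -4.60.

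By line, BRM014 raised CXCL8 (6.12 ± 0.37), the calcium-binding protein S100A9 (5.75 ± 0.38) and GDF15 (5.64 ± 0.21) in NCI-H1048 and lowered the phospholipase PLA2G4D (-4.39 ± 0.24), AZGP1 (-3.85 ± 0.31) and C5orf58 (-3.63). DESeq2 did not call S100A9 there (adjusted p = 0.657). In that line 13 of 18 epithelial genes rose (13 adjusted over the list alone; adjusted p = 2.4e-14, and 0.00777 with an estimated correlation). CDH1 stood at 3.42 ± 0.10. There 16 of 20 cholesterol synthesis genes rose with 1 lower (17 and 1 adjusted over the list alone; adjusted p = 4.5e-09, and 0.0245 with an estimated correlation). In NCI-H211 the neurotrophin BDNF (3.87 ± 0.32) rose, as did PSTPIP2 and SH2D6, and the microvillus protein villin, VIL1 (-5.67 ± 0.48), the receptor phosphatase PTPRZ1 (-4.61 ± 0.47) and the ionocyte transcription factor FOXI1 (-3.96 ± 0.20) fell. There 25 of 26 DNA replication and E2F targets fell (25 adjusted over the list alone; adjusted p = 1.4e-24, and 0.00324 with an estimated correlation). Cholesterol synthesis went the other way than in NCI-H1048, with 11 of 20 lower and 0 higher (11 and 1 adjusted over the list alone; adjusted p = 0.00287, and 0.249 with an estimated correlation). In NCI-H526 RGS4, a regulator of G protein signalling (6.76 ± 0.25), the somatostatin receptor SSTR1 (6.25 ± 0.32) and the phosphatase PTPN14 (4.40 ± 0.32) rose, and TAFA3 (-5.98 ± 0.68), ANXA1 and NUGGC (-4.41 ± 0.31) fell. Of 16 p53 targets 10 rose and 1 fell in this line (11 and 1 adjusted over the list alone; adjusted p = 3.5e-04, and 0.0336 with an estimated correlation). FAS stood at 2.59 and CDKN1A at 1.11. In COR-L311 PTPRZ1 (5.52 ± 0.29), TP53I11 (5.29 ± 0.35) and WNT4 (3.38 ± 0.27) rose, while PHLDA1 (-5.85 ± 0.45), COL2A1 (-5.26) and the claudin CLDN19 (-5.15 ± 0.38) fell. In this line 9 of 15 MHC class I genes fell with 1 higher (9 and 1 adjusted over the list alone; adjusted p = 4.2e-07, and 0.139 with an estimated correlation). HLA-C stood at -2.07 ± 0.10. Mitochondrial-encoded transcripts, whose reads can be shared with nuclear copies, moved with BRM014 as well: 6 of 10 rose in NCI-H211 (8 adjusted over the list alone; adjusted p = 0.00144, and 0.483 with an estimated correlation). In NCI-H526 9 of them fell (9 adjusted over the list alone; adjusted p = 0.00341, and 0.571 with an estimated correlation), and in COR-L311 8 rose (9 adjusted over the list alone; adjusted p = 4.0e-05, and 0.378 with an estimated correlation). Beside them, the tuft cell list was called higher in NCI-H211 and NCI-H526 and lower in COR-L311 (adjusted p = 0.339, 0.683 and 0.238 with an estimated correlation). Mitochondrial transcripts made up 2.11% to 7.46% of the counts of a library.

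The BRM014 effect differed between lines for 8548 genes, with the line effects at least 1 apart on the log2 scale for 4655. The annexin ANXA4 changed by 0.36 in NCI-H1048, 0.99 in NCI-H211, -0.32 in NCI-H526 and -3.26 in COR-L311, and ALDH1A1, a retinaldehyde dehydrogenase, by 0.86, -2.67, -2.43 and -4.42 in the same order. ADGRG6, an adhesion G protein-coupled receptor, rose by 1.14, 2.45 and 3.73 in NCI-H1048, NCI-H211 and NCI-H526 and fell by 1.25 in COR-L311, and the phosphatase PTPRJ rose by 1.18, 2.15 and 0.40 and fell by 1.48. PHF20L1 rose by 2.60 in NCI-H211. Of 12208 genes called in any line, 2202 were called in opposite directions. By pair of lines, opposite calls lay above the number for independent lists only in NCI-H1048 and COR-L311 (755 against 534). They lay below it in every other pair, for instance at 502 against 1014 in NCI-H211 and NCI-H526. Calls in the same direction lay above the independent number in each pair. Line effects correlated across 11453 genes at 0.06 to 0.42, highest for NCI-H211 and NCI-H526.

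The remaining lists were not called by camera in the mean of 4 lines with either compound, apart from the cholesterol, IGF, tuft cell and non-canonical BAF lists above, which were called with WA-68-VQ71. With BRM014 4 of 20 cholesterol genes rose and 4 fell (5 and 4 adjusted over the list alone). Of 14 IGF and receptor tyrosine kinase genes 4 rose and 2 fell (4 and 3 adjusted over the list alone). BICRAL (1.33 ± 0.07) and BICRA (0.27) of the non-canonical BAF list rose while BRD9 fell (2 and 1 adjusted over the list alone). Counts that follow give higher and lower members, over all genes and then adjusted over the list alone. For WA-68-VQ71 they were 0 and 2, then 1 and 2, of 17 shared SWI/SNF subunits, 1 and 3, then 2 and 3, of 18 neuroendocrine genes, and 1 and 0, then 2 and 0, of 8 ciliated cell genes. Of 15 Notch pathway genes they were 2 and 2, then 4 and 4. They were 1 and 1 in either adjustment of 16 p53 targets, and 1 and 0 of 17 mesenchymal genes and of 16 replication-dependent histones. For 19 ATF4 and unfolded protein response genes they were 0 and 0, then 2 and 5, and for 11 Wnt targets 0 and 0, then 1 and 0. No member was called by edgeR, in either adjustment, of the lists for canonical BAF, PBAF, basal cells, secretory cells, ionocytes, alveolar cells, immune cells, fibroblasts and endothelium, interferon response, MHC class II and mitochondrial-encoded transcripts. For BRM014 the counts were 2 and 1, then 3 and 1, of 5 canonical BAF subunits, with ARID1B at 0.46, 1 and 0 of 4 PBAF subunits in either adjustment, and 2 and 5, then 4 and 6, of 17 shared subunits, with ACTL6A at -0.57. They were 3 and 5 of 18 neuroendocrine genes, with NCAM1 at -1.03 ± 0.05, 1 and 4 of 17 mesenchymal genes, 4 and 1 of 8 ciliated cell genes, 2 and 1 of 5 alveolar genes, and 1 and 1 of 7 basal genes, each in either adjustment. Likewise 0 and 1 were called of 4 ionocyte and of 3 secretory genes, 0 and 0 of 6 fibroblast and endothelial genes, and 0 and 2 of 9 MHC class II genes. The counts were 5 and 8, then 7 and 8, of 28 interferon response genes, 7 and 2, then 7 and 3, of 19 ATF4 and unfolded protein response genes, and 2 and 3, then 2 and 4, of 11 Wnt targets. They were 5 and 4 of 16 histones, 7 and 1 of 16 p53 targets, 4 and 8 of 15 Notch genes in either adjustment, and 2 and 0, then 0 and 0, of 10 mitochondrial-encoded transcripts. The immune cell list had 2 measured genes, too few for camera, and neither was called.

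Compared directly, BRM014 and WA-68-VQ71 differed for 6347 genes in the mean of 4 lines, 3210 higher and 3137 lower with BRM014, of which 825 lay at least 1 apart on the log2 scale. With lines as replicates the count was 52. Of 24 mitosis genes 23 were lower with BRM014 than with WA-68-VQ71 and 0 higher (24 and 0 adjusted over the list alone; adjusted p = 2.2e-22, and 0.00264 with an estimated correlation). AURKB stood at -0.68 and KIF20A at -0.61. Of 26 DNA replication and E2F targets 20 were lower and 2 higher (20 and 2 adjusted over the list alone; adjusted p = 3.2e-11, and 0.0697 with an estimated correlation). The ribosome biogenesis list was lower (14 of 24, with 2 higher; 16 and 2 adjusted over the list alone; adjusted p = 2.4e-06), and so were MHC class I genes (10 of 15, with 2 higher; 10 and 2 adjusted over the list alone; adjusted p = 3.7e-05). Both had an adjusted p of 0.108 with an estimated correlation, as had epithelial genes, which were higher (9 of 18, with 2 lower; 10 and 2 adjusted over the list alone; adjusted p = 1.3e-04), with KRT18 at 2.00 ± 0.05 and KRT8 at 1.80. Heat shock genes (6 of 12 lower, 7 adjusted over the list alone, adjusted p = 0.00345, and 0.132 with an estimated correlation) and cholesterol synthesis genes (7 of 20 lower and 1 higher, 8 and 1 adjusted over the list alone, adjusted p = 0.0111, and 0.273 with an estimated correlation) were lower. The tuft cell list did not differ by camera (8 of 32 higher and 9 lower, 8 and 9 adjusted over the list alone; adjusted p = 0.609). HMOX1, GSN, THBS1, PTGS2, PTPN14 and SNTB1 were among the genes named by rule as higher with BRM014, and COL2A1, AZGP1, RELN, B3GAT1 and NID1 among those lower. The homeobox gene DLX5 had 0 counts with WA-68-VQ71 in COR-L311 and was at least 196-fold higher with BRM014. PTPRT and SRL had a group at 3 counts or fewer in a line, and VIL1 had 4 counts with BRM014 and 8 with WA-68-VQ71 in NCI-H1048. Each of these genes lost its call without some single library. For PTPRT this was NCI-H211 WA-68-VQ71 replicate 2 (adjusted p = 0.9999 without it) and for SRL NCI-H1048 WA-68-VQ71 replicate 1 (0.0892) or 2 (0.0970). For VIL1 it was either NCI-H1048 BRM014 replicate, NCI-H211 BRM014 replicate 2, replicate 1 of WA-68-VQ71 in any line, or replicate 2 of it in NCI-H1048 or NCI-H211, with an adjusted p from 0.0509 to 0.383.

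The compounds share their DMSO libraries, which alone makes their effects alike. In the mean of 4 lines 414 genes were called higher with both compounds and 391 lower with both, against 102 and 81.3 for independent lists, and 61 were called in opposite directions, against 183. Among genes called with WA-68-VQ71, 75% of those higher and 85.4% of those lower were called the same way with BRM014. Fold changes correlated at 0.51 across 11453 genes, against 0.50 for simulated unchanged groups on the same controls, and their covariance was 0.0347 against 0.0042, a difference of 0.0305. With DMSO replicate 1 of each line as control of WA-68-VQ71 and DMSO replicate 2 as control of BRM014, the correlation was 0.40, with 135 genes higher and 59 lower with both. With the controls exchanged it was 0.39, with 143 and 110. Of the 805 genes called the same way with both compounds, the change was larger with BRM014 in 703, with a median ratio of 1.88 between the log2 fold changes. By line 795 genes were higher and 335 lower with both in NCI-H1048, 358 and 361 in NCI-H211, 39 and 32 in NCI-H526 and 5 and 10 in COR-L311, with 35, 31, 17 and 3 in opposite directions. Independent lists would give 141 and 51.8, 72.9 and 70.9, 7.61 and 6.58, and 0.998 and 1.37 in the same order, with 175, 144, 14.2 and 2.36 in opposite directions. Opposite calls thus lay below the independent number in NCI-H1048 and NCI-H211 and not in NCI-H526 or COR-L311. Fold changes correlated at 0.63, 0.54, 0.32 and 0.30, against 0.50 for simulated unchanged groups in each line, and the covariance exceeded the simulated one by 0.118, 0.105, 0.0282 and 0.0297. With the 2 DMSO libraries of a line divided between the compounds, the correlation within the line was 0.56, 0.46, 0.18 and 0.12 in the same order (mean of the 2 divisions). The calls by line were not repeated with divided controls, so part of the shared calls within a line may come from the shared controls.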

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

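Among the tests in this part, the exchange of DMSO and BRM014 libraries in NCI-H211 and the absence of a WA-68-VQ71 effect in COR-L311 were chosen only after the result was seen. Each gene listed first had an effect that differed between the 4 lines by the F test, and no group held enough libraries for a search for outlying samples.

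With WA-68-VQ71 the effect of 1010 genes differed between lines. Given as the highest minus the lowest line effect on the log2 scale, the named genes among them were POU2F3 (1.57), POU2AF2 (1.05), SOX9 (1.13), CCDC9B (2.08), DUSP8 (2.52), SNCAIP (1.48), PRR15 (1.61), ST18 (2.11), NEB (2.39), PSD2 (2.14) and ANXA1 (1.89). From the genes of single lines came CRYM (3.37), AJUBA (2.37), CEMIP (1.61), RPS6KL1 (2.64), BIK (2.03), CLIC5 (1.80), MME (1.06), RARG (1.54) and REEP2 (0.96), and from the test between lines ELF3 (2.12), CLDN4 (3.51), MYH9 (1.34), RASSF6 (2.57) and CEMIP2 (1.74). Where a group lay at or under 3 counts the adjusted p of the F test stands in place of a spread: YAP1 8.4e-04, FAM3B 0.0450, ANKRD1 0.00279, GDF15 2.0e-05, C5orf58 0.00702 and PLA2R1 0.00110.

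With BRM014 the effect of 8548 genes differed between lines. The spreads were 1.90 for POU2F3, 1.60 for POU2AF2, 3.19 for POU2AF3, 1.72 for SOX9, 4.40 for MYC, 0.57 for BRD9, 1.15 for SMARCA2 and 0.37 for SMARCA4. Genes named for their mean effect spread by 2.40 (HMOX1), 2.09 (GSN), 3.15 (LTBP1), 3.84 (SEMA3C), 3.04 (KRT18), 3.37 (COL2A1), 2.29 (AZGP1), 4.51 (ANXA1), 3.62 (RELN), 2.39 (DCHS2) and 1.91 (TMPRSS3). Genes named in a line spread by 4.65 (PSTPIP2), 3.98 (SH2D6), 10.13 (PTPRZ1), 3.87 (PTPN14), 3.48 (WNT4), 9.42 (PHLDA1) and 4.61 (CLDN19), and those of the test between lines by 4.24 (ANXA4), 5.28 (ALDH1A1), 4.98 (ADGRG6), 3.63 (PTPRJ) and 2.71 (PHF20L1). With a group at or under 3 counts the adjusted p was 5.2e-06 for YAP1, 3.1e-10 for THBS1, 1.3e-12 for KLHDC7A, 9.3e-05 for PTGS2, 3.4e-07 for KCNS3, 0.00284 for B3GAT1, 1.2e-09 for GDF15 and 0.00201 for PLA2G4D. It was 0.0307 for C5orf58, 7.0e-09 for BDNF, 1.0e-04 for VIL1, 5.9e-13 for FOXI1, 5.5e-08 for RGS4, 4.7e-16 for SSTR1, 8.4e-09 for TAFA3 and 2.0e-10 for TP53I11.

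With BRM014 15 POU2F3 programme genes fell and 3 rose in NCI-H1048, whereas 18 rose and 6 fell in NCI-H211, and the calls of the whole list were lost with an estimated correlation (adjusted p = 0.281 and 0.339). RNA of another line in these libraries is argued against by its low share. Genes abundant in a source line and near 0 in the recipient reached median shares of at most 0.0664% in NCI-H1048 and 0.0825% in NCI-H211. The former is 0.104% of the share computed from the POU2F3 fall for a source without POU2F3. The 3 other lines had more POU2F3 with DMSO than NCI-H1048, so their RNA could not cause that fall, whatever the share. In NCI-H211 the rises would need a median share of 41.8% from NCI-H526, of which 0.109% was reached. From NCI-H1048 and COR-L311 they would need 170% and 118%, more than any mixture can hold. The choice among the scalings tried is argued against as a cause: with library sizes only or RLE factors at least 15 members were still called lower in NCI-H1048 and 18 higher in NCI-H211. These scalings moved the median of all genes by at most 0.07 in size, so an error that they share was not tested. Exchanged DMSO and BRM014 libraries in NCI-H211 would reverse genes that move alike elsewhere, but 449 of 550 genes called the same way in the 3 other lines moved that way in NCI-H211 too (81.6%). A difference between the cell lines themselves stays open. It may be biological and was found and tested on the same data.

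MYC rose and MYCN fell in NCI-H526 with BRM014. Genes abundant in another line and near 0 in NCI-H526 reached at most 9.58% of the share of foreign RNA that the MYC level would need, with NCI-H211 as the source, a median share of 0.0800% (quartiles 0.0041 and 0.134) against 0.835%. Under library sizes only and RLE factors the smaller of both changes kept a size of 1.76 on the log2 scale. These scalings moved the median of all genes in this comparison by only 0.039 and -0.013, so changes of this size could not have been lost. The choice among them thus made little difference, and an error that they share was not tested. Contamination is argued against as the whole cause, and an effect of the treatment stays open. MYCN at 464 CPM remained far above MYC at 3.04 CPM with BRM014.

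WA-68-VQ71 called fewer genes in COR-L311 and NCI-H526 than in NCI-H1048. A larger spread between replicates is argued against, because the SD of log2 fold changes left after subtracting their error was at most 41.5% of that in NCI-H1048. It was 0.0951 in NCI-H526 and 0.0698 in COR-L311, against 0.229. Lower depth is argued against by the totals. The DMSO and WA-68-VQ71 libraries averaged about 17259300 counts in NCI-H1048, 16017932 in NCI-H526 and 16955261 in COR-L311. With all libraries thinned to 14147672 counts these lines gave 1453, 101 and 21 genes, 14.4 times as many in NCI-H1048 as in NCI-H526. Thinning libraries of such like depth could hardly have closed the gap. A compound without any effect in COR-L311 would leave 50% of shared genes moving the common way, whereas 106 of 147 genes called the same way in at least 2 other lines did so (72.1%). This lies below the bound of 75% set for the test, over genes that are not independent, so the test was undecided, though 24 genes were called in COR-L311, among them ST18. A weaker response of these lines, or less active compound in them, may account for the pattern, and the data do not separate these.

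For the counts of called genes, libraries were divided within lines in 25 ways drawn at random, the real one included. The real division gave as large a count in 1 of 25 for WA-68-VQ71 in the mean (1010, highest other 516), BRM014 in the mean (7689, highest other 2415), the compounds against each other (6347, highest other 995) and the BRM014 effect between lines (8548, highest other 7126). This is the smallest share that 25 divisions can give, so chance is argued against there but not excluded. Divisions that mix both treatments in a group also widen its spread, which can lower their counts. The division with 7126 genes kept the DMSO and BRM014 libraries of NCI-H1048, NCI-H211 and NCI-H526 together, with the labels exchanged in NCI-H526, and so carries the treatment effect. For the WA-68-VQ71 effect between lines 4 of 25 divisions gave as many genes (1010, highest other 1222), so chance cannot be excluded by this count. The 3 other divisions as large all kept the DMSO and WA-68-VQ71 libraries of NCI-H1048 and of NCI-H211 together, with the labels exchanged in 1 of these lines, and so carry the treatment effect with its sign reversed there.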

How the results depend on the processing

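The alternatives in this part were all planned. In tests of named genes the direction and the side of the threshold held in 2298 cases across alternatives and in 1732 with a library left out, the call was lost in 95 and 97 and gained in 49 and 7, and the direction turned in 9. Counts of genes or lists stayed within 1.5 times in 134 and 126 cases and moved by more in 29 and 18. No called list changed the sign of its median under library sizes only or RLE factors, and no scaling moved the median of all genes by more than 0.07 in size. The causes of the changes that follow were not tested, except that a further threshold calls fewer genes by construction. Fits of genes with a library left out also tested more genes, so the loss of a call there need not come from that library alone.

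Without NCI-H1048 the mean change with WA-68-VQ71 of POU2F3 was 0.079 (adjusted p = 0.195) and of POU2AF2 0.18. The mean of SOX9 with BRM014 was -0.26 without NCI-H211 and -0.17 without NCI-H526, and that of MYC was -0.42 without NCI-H526 and -0.092 on log2(FPKM + 1). Both means were positive in the main fit, so their direction turned. Between the compounds the mean of SOX9 was 0.27 without COR-L311, of MYC -0.11 without NCI-H526 and of SMARCA2 0.25 without NCI-H211. POU2F3 with WA-68-VQ71 lost its mean call with library sizes only (adjusted p = 0.0806) and without a filter (0.0852).

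Lines as replicates gave 0 genes for WA-68-VQ71 (343 at an unadjusted p below 0.05, smallest adjusted p 0.948), 655 for BRM014 and 52 between the compounds, and 9 lists for WA-68-VQ71. DESeq2 on all libraries called 1238 and 7528 genes in these means. A log2 fold change of at least 1 in size left, for WA-68-VQ71, 45 genes in the mean and 511, 140, 27 and 8 in NCI-H1048, NCI-H211, NCI-H526 and COR-L311. It left 1091 for BRM014 in the mean and 1635, 2296, 1857 and 1457 by line, 825 between the compounds, and 567 and 4655 in the tests between lines. For WA-68-VQ71 the mean gave 409 genes without NCI-H211, NCI-H211 gave 1942 from its own 6 libraries, and NCI-H526 gave 257 from its own, 165 without a filter and 47 on log2(FPKM + 0.1). COR-L311 gave 73 without a filter, 43 with DESeq2 and 40 on log2(FPKM + 1). An estimated correlation left 1 list for WA-68-VQ71 and 3 for BRM014, and fry called 25 lists for BRM014 in its directional and 28 in its mixed form.

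With 1 library left out, whose partner is assumed to vary like the other groups, counts ran from 667 to 1066 for WA-68-VQ71 in the mean, 848 to 1165 in NCI-H1048, 300 to 386 in NCI-H211, 28 to 40 in NCI-H526 and 9 to 30 in COR-L311. For BRM014 they ran from 7123 to 7723 in the mean, 3451 to 5269 in NCI-H1048, 5299 to 5535 in NCI-H211, 4327 to 4753 in NCI-H526 and 2485 to 3119 in COR-L311. Between the compounds the range was 5693 to 6376, in the tests between lines 714 to 1120 and 7510 to 8776, and for lists 13 to 16 and 11 to 13.

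Replicate numbers are shared by the groups, and the labels do not say what they mark. Deviations of same-numbered libraries of a line correlated at -0.09 to 0.25, over 0.1 in 5 of 12 pairs of groups, among them all those of NCI-H526 (0.13, 0.16 and 0.25). Over all 66 pairs of groups, different lines included, they ran from -0.36 to 0.29, and the numbers were not taken to pair the samples. With the replicate number as a block the mean of WA-68-VQ71 gave 1153 genes and 15 lists and that of BRM014 7770 genes and 11 lists. The block within lines gave 1212 and 7818 genes, NCI-H526 gave 110 and 6140 with the replicate number as a block, and no count moved by more than 1.5 times. Depth limits genes near the floor, such as NEUROD1 in NCI-H1048 and NCI-H211 and YAP1 in COR-L311.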

Other observations

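Among the tests in this part both tests of hypotheses were planned, whereas the genes of the next 3 sentences were chosen only after their values were seen, and their calls were not repeated with single libraries left out. Beyond the genes named by rule, BRM014 raised HES1, a repressor downstream of Notch, in all 4 lines, with log2 fold changes from 1.81 in COR-L311 to 3.28 in NCI-H211. The Notch coactivator MAML2 (1.16 to 2.89), the tight junction protein gene CGN (1.05 to 2.19), AHRR, the repressor of the aryl hydrocarbon receptor (1.31 to 2.31), and CUEDC1 (1.38 to 2.36) also rose in each line. Falls in each line were seen for NES, which encodes the progenitor filament protein nestin (-1.74 to -1.42), the adhesion molecule MCAM (-2.75 to -0.92), the transcription factor KLF15 (-2.24 to -1.05), PTTG1, which encodes securin (-1.18 to -0.75), FGF13 (-1.41 to -0.89) and the neuropeptide gene NMU (-1.31 to -0.73).

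A hypothesis was that BRM014 lowers the genes specific to a line, defined from the WA-68-VQ71 libraries as at least 4-fold above each other line. In COR-L311 66 of 139 such genes fell and 19 rose, with a median log2 fold change of -0.50, and in NCI-H526 60 of 162 fell and 29 rose, with a median of -0.24, both below all 10000 random lists of matched expression. In NCI-H1048 150 of 385 rose and 70 fell, with a median of 0.25, above all random lists, and in NCI-H211 44 of 162 rose and 38 fell, with a median of 0.09 at the 99.98th percentile. The random lists were matched on expression only and treat genes as independent, so their spread may be too narrow and these ranks too extreme. Holding in 2 of 4 lines, the test of whether BRM014 lowers genes specific to a line was undecided. Genes raised by WA-68-VQ71 in a line could enter its list. With divided controls the WA-68-VQ71 effects correlated with those of BRM014 at 0.56 in NCI-H1048 and 0.46 in NCI-H211. The positive medians there may thus come in part from the choice of genes, which was not tested. Whether the hypothesis applies to COR-L311 and NCI-H526 alone stays open.

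A further hypothesis was that both compounds act on the same genes within a line, so that the effects of WA-68-VQ71 should correlate best with those of BRM014 in the same line. With DMSO libraries divided between the compounds, the mean correlation across 11453 genes was 0.56 in NCI-H1048, against at most 0.12 with BRM014 in another line, and 0.46 in NCI-H211, against at most 0.28. In NCI-H526 it was 0.18, against 0.21 with BRM014 in NCI-H211, and in COR-L311 0.12, against 0.16 with NCI-H211. The prediction that both compounds act on the same genes within a line thus held in 2 of 4 lines and cannot be told apart from an effect shared between lines in the remaining ones, where WA-68-VQ71 changed few genes.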
